A study of Rattus norvegicus with 4 samples.

How the data were processed

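Total RNA from the small intestine of individual male Wistar rats was labelled with Cy3 and hybridised to one-colour Agilent rat oligonucleotide arrays, per the labels. The 2 groups were control rats, which drank tap water, and compost rats, whose tap water held 1% (v/v) compost extract for 12 weeks from 3 weeks of age. Each group had 2 rats, each with 1 array. The labels describe the tissue as small intestine without Peyer's patches and do not say which part of the small intestine was taken. The labels treat the replicates as separate rats. All 4 arrays lay on 1 slide and carried the same scan, with the control rats at positions 1 and 2 and the compost rats at positions 3 and 4, so array position and group cannot be told apart and no batch could be fitted.

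The deposited scanner files held a spot intensity from Agilent Feature Extraction 9.1.3.1, which the software had detrended and background-subtracted, per the file headers, on a linear scale and not scaled between arrays. The same files held the raw mean intensity of each spot, its local background intensity and flags for signal well above background, saturation and outlier spots. The authors' deposited value table held the same processed intensity, rounded to 3 significant digits: the largest difference on any array was under 0.5% of the scanner value. Its column medians over all spots were 80.2 and 79.4 for the control arrays and 102 and 73.9 for the compost arrays, on the linear scale and with no centring, so none of its scale, centring or direction stayed unknown. Each array had 45018 spots, of which 1639 were controls and were left out. The remaining 43379 gene spots stood for 41012 probes. Between 66.5% and 71.0% of gene spots were well above background, 2 to 5 spots per array were saturated and 7 to 11 were outliers. Outlier spots were left out, which removed 31 probes, and saturated spots were kept.

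The log2 of the processed intensity was averaged over the spots of a probe, and the 75th percentile of the array over all gene probes was subtracted. Probes well above background on at least 2 of the 4 arrays were kept, which left 28415 probes. Compost was compared with control by limma 3.58.1 in R 4.3.3 with lmFit and eBayes, two-sided, with Benjamini-Hochberg adjustment over all probes kept and a threshold of 0.05. A count without a test gave the probes whose nearest arrays of the 2 groups lay at least 1 log2 unit apart, in each direction, and the same count was made for the other 2 ways to divide the 4 arrays into pairs. By chance each direction of non-overlap has a share of 16.7% for a single gene. Genes of a list can vary together and then separate together, so a count over a list is not a test. Every log2 difference is compost minus control, and its error is the standard error of the limma model. The number of arrays limits the precision.

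A gene was represented by its kept probe with the highest mean over the 4 arrays, which gave 24311 genes or unnamed transcripts, 11482 of them with a usable symbol. Names on the array were old and were updated through a table of the GRCr8 assembly, used for names alone: 11000 probes matched by accession, 5181 by symbol and 3455 by a synonym, and 21376 kept the name in the file. No genome sequence was used, so positions are not given. Where every array of a group was not well above background, only a bound is given: the mean of the brighter group against the mean, over the dim arrays, of the higher of the probe's own value and the lowest value among probes well above background on that array. Such a bound holds for the processed intensity alone: with normexp background correction, all 24 bounds computed for genes and immunoglobulin probes exceeded the fold measured.

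Before the data were examined, 40 gene lists were fixed for digestive, metabolic, immune and secretory functions, for markers of other cell types and neighbouring tissues, and for signs of handling. The list of eosinophil markers had fewer than 5 measured members and was left out, so that 39 lists were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the 39 lists. The same tests were run with an estimated correlation and with fry. The rule for named genes took the 12 genes with the largest difference in each direction among those that passed. Since none passed, it took the 12 with the smallest unadjusted p among those with a difference of at least 1 log2 unit in that direction. Up to 4 members with the smallest p were named from each list described.

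The fits were tested on simulated data with the values of these arrays. For compost against control, 200 of 28415 probes were shifted in each of 20 draws. At 2-fold and at 4-fold none of the shifted probes were recovered, at 8-fold 76.9% were and at 16-fold 90.6% were, with 0.05, 0.15, 7.60 and 9.85 false calls per draw. A list shifted by 1 log2 unit was called in 20 of 20 draws at the preset correlation and in 0 of 20 with an estimated correlation. With no shift, 0.05 lists per draw were called. The simulated noise was independent between probes, so that genes of a list did not vary together. These list rates therefore do not carry over to real lists whose genes vary together.

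Alternatives covered the percentile over probes well above background on all arrays, quantile and cyclic loess scaling, normexp background correction with an offset of 50 on the raw intensities followed by quantile scaling, the deposited value table, the filter on dim probes, saturated or outlier probes, 1 value per gene, a variance trend with robust estimation, the replicate number as a block, each array left out in turn, the 2 other list tests, and a threshold of 0.10. Each alternative was planned before the data were examined.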

Results

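The comparison addressed how compost extract taken by mouth affects gene expression in the rat gut. Male Wistar rats, an outbred stock, drank tap water with 1% (v/v) compost extract or tap water alone. The extract was a heated watery dilution of a fermented compost. Treatment began at 3 weeks of age and lasted 12 weeks. Small intestine freed of Peyer's patches, the large clusters of lymphoid follicles in the gut wall, was profiled from 2 control rats and 2 compost rats on 1 array each. The median spot intensity was 88.4 and 87.2 on the control arrays and 113 and 80.8 on the compost arrays, and the share of gene spots well above background was 68.3% and 70.7% against 71.0% and 66.5%. Across the 28415 probes kept, which are not independent replicates, Pearson's r was 0.986 between the control arrays, 0.981 between the compost arrays and 0.981 to 0.988 between arrays of different groups.

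Genes of B cells, plasma cells and lymphoid follicles were higher in the compost rats than in the control rats, by a median of 2.14-fold and 2.06-fold for the 2 lists, and by 1.52-fold and 1.69-fold with normexp background correction. Smaller upward shifts were measured for genes of sterol biosynthesis, of microbial sensing and inflammatory mediators and of the unfolded protein response. Genes of absorptive enterocytes, the cells that digest and take up nutrients, were lower by a median of 1.29-fold, and genes of fatty acid oxidation by 1.21-fold. Of 39 gene lists tested with limma's camera, 14 were called higher and 4 lower in compost. Of these 18 calls, 0 were made with an estimated correlation (lowest adjusted p = 0.386 with an estimated correlation) and 0 by fry (lowest adjusted p = 0.0774). No single probe passed, neither higher (0) nor lower (0), in limma's test with adjusted p under 0.05 or under 0.10. With quantile scaling Doc2b, Becn2 and Muc19 had an adjusted p under 0.10 (adjusted p = 0.0689 for each).

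The other 2 ways to pair the 4 arrays, which mix compost and control rats, called 14 and 9 lists. The B and plasma cell, lymphoid follicle, sterol biosynthesis, microbial sensing, unfolded protein response, absorptive enterocyte and fatty acid oxidation lists, 7 in all, were called without each of the 4 arrays in turn and had a larger median under the real grouping than under both others. The remaining 11 calls were lost without at least 1 array. Lists called in the other pairings were not put through the same check, so no chance count stands beside the 7.

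**Figure D1:**
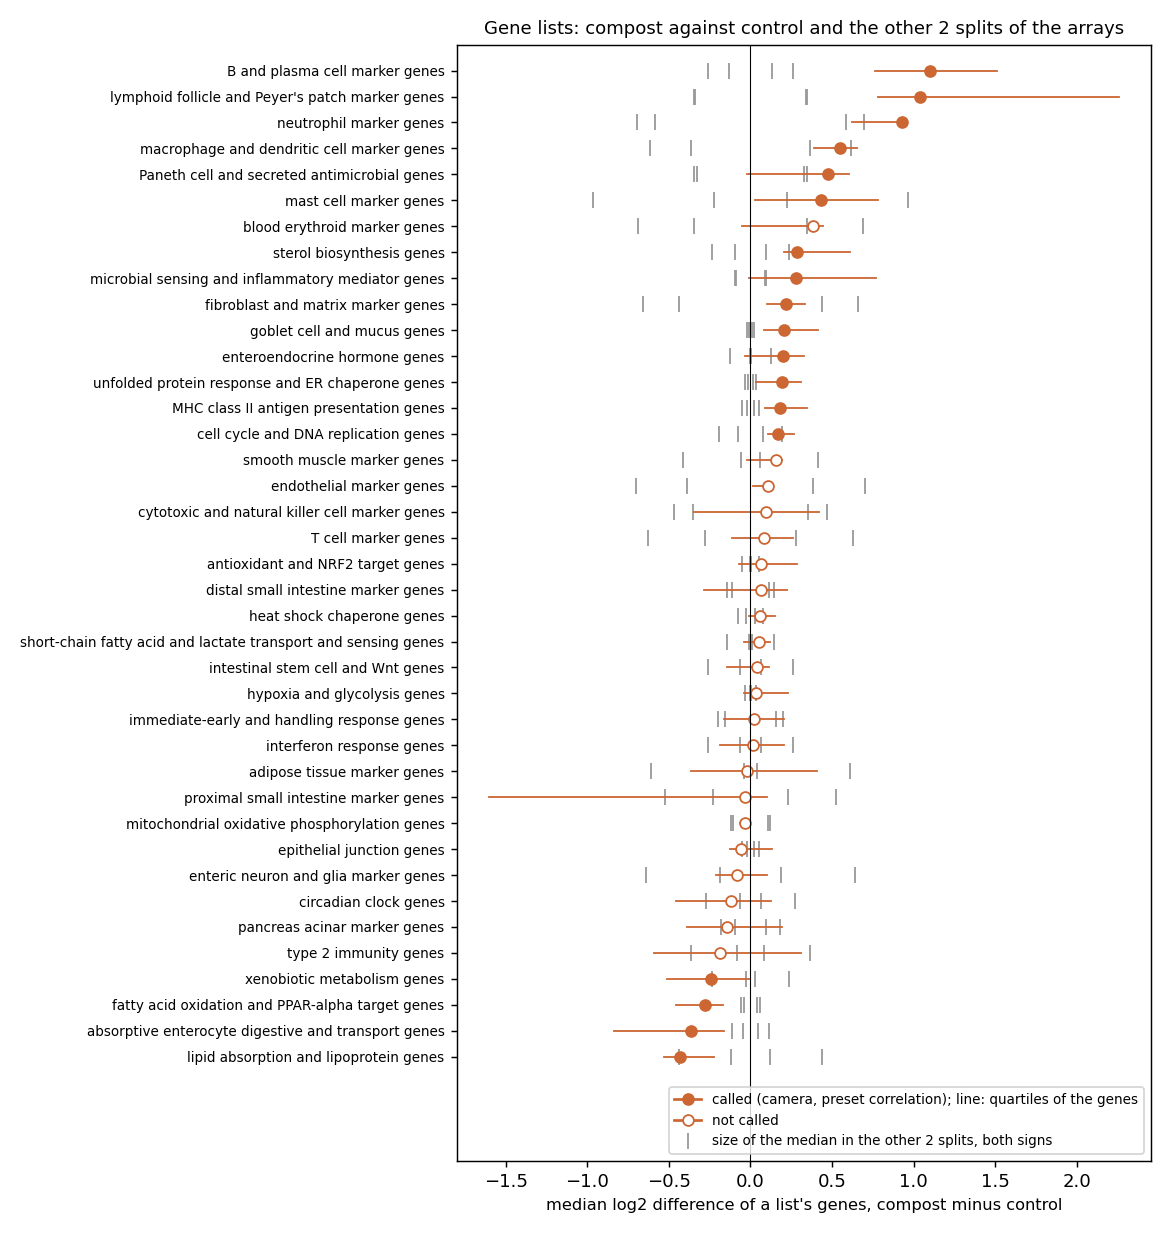
Median log2 difference (compost minus control, x axis) of the measured genes of each of 39 lists (y axis), with the quartiles of the genes as a line, filled where limma's camera called the list at the preset correlation; grey ticks give the size of the median in the other 2 pairings of the 4 arrays. The B and plasma cell list lies at 1.10 and the follicle list at 1.04, while the other pairings reach 0.26 and 0.35 in size for them.

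Among single genes, the 12 higher and 12 lower in compost with the smallest unadjusted p are given as values that did not pass. Among the higher genes were Cxcl13, the chemokine that draws B cells into follicles, at 9.45-fold (log2 difference 3.24 ± 0.30 SE, adjusted p = 0.294 by limma), Eaf2, a transcription elongation cofactor (1.91 ± 0.18), the lymphocyte lysophospholipid receptor Gpr174, Lag3, an inhibitory receptor of activated T cells (1.47 ± 0.20) and the T and natural killer cell adhesion molecule Cd2 (1.60 ± 0.23, well above background in 1 of the 2 control rats). Gpr174 was not well above background in either control rat and was at least 2.08-fold higher in compost. Doc2b, a calcium sensor of vesicle release, Becn2, an autophagy protein, and Nova1, a neuronal splicing factor, were also not well above background in either control rat, and were at least 3.14-fold, 3.79-fold and 4.89-fold higher (adjusted p = 0.103, 0.103 and 0.245 by limma). The others were Mrgprx3, at least 2.02-fold, Wfdc18, at least 1.45-fold, the ribosomal protein gene Rpl3l (1.37 ± 0.21) and the matrix protease Adamts5 (1.15 ± 0.18, well above background in 1 of the 2 control rats). The gel-forming mucin gene Muc19 and the nucleoside transporter gene Slc28a3 were not well above background in either compost rat and were at least 3.87-fold and 3.46-fold lower (adjusted p = 0.124 and 0.306 by limma). The same held for Rnf222, Dusp13b and Cfap161, which were at least 3.39-fold, 1.77-fold and 1.63-fold lower. Iyd, which recovers iodide from iodotyrosines, was well above background in 1 of the 2 compost rats (-3.22 ± 0.52, and -2.54 without control replicate 2). Log2 differences were -1.22 ± 0.22 for G6pc1, the glucose-6-phosphatase of glucose release, -1.23 ± 0.20 for Apoa5, a regulator of plasma triglycerides, -1.16 ± 0.18 for Edn3 and -1.13 ± 0.18 for Gnai1, and they were -1.74 ± 0.18 for Prss35 and -2.11 ± 0.27 for Rsf1. The second kept probe of G6pc1 gave -1.19 ± 0.26, and the other genes had 1 kept probe each. With normexp background correction, which adds an offset of 50, all 24 differences were smaller, with a median size of 0.99 against 1.92. All 11 bounds given here then exceeded the fold measured, at 1.95-fold for Doc2b, 1.36-fold for Gpr174 and 1.79-fold for Muc19, so that they hold for the processed intensities alone.

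**Figure D2:**
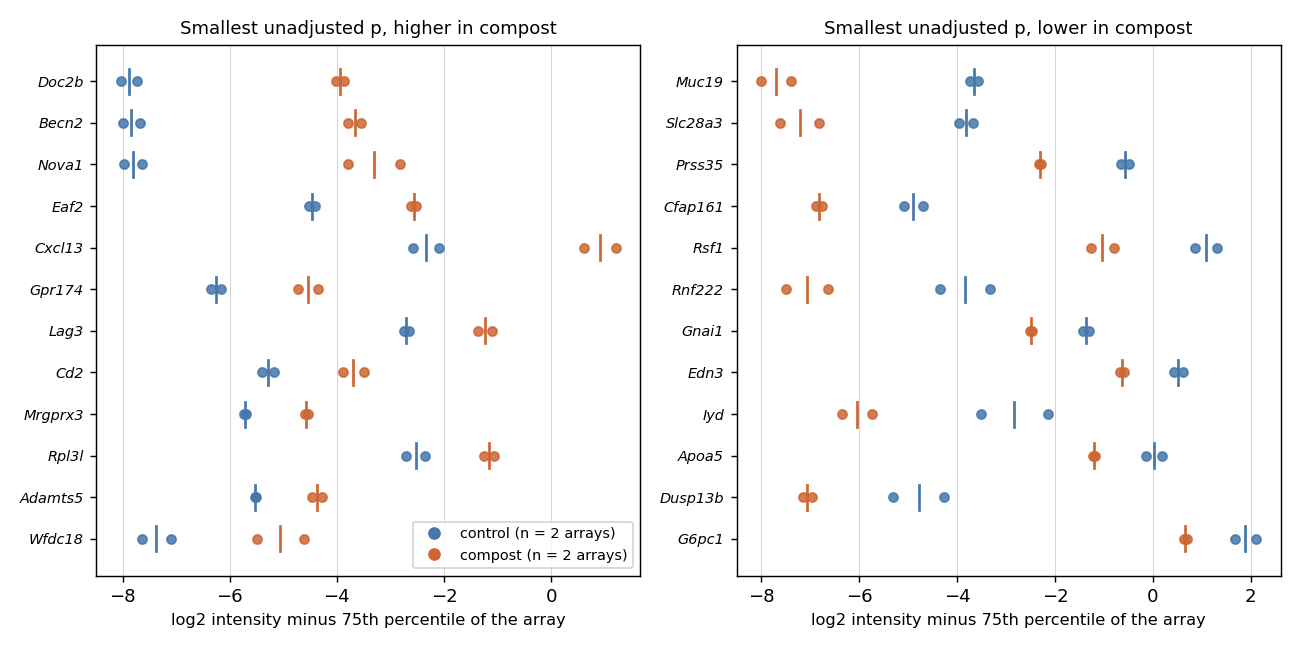
Log2 intensity minus the 75th percentile of the array (x axis) for the 24 genes with the smallest unadjusted p among those at least 1 log2 unit apart (y axis); each point is 1 rat, and a vertical line marks the mean of the 2 rats of a group. Cxcl13 lies at -2.58 and -2.09 in the control rats and at 0.61 and 1.20 in the compost rats.

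No probe passed among the 28415 tested, while 913 had an unadjusted p under 0.05, 401 of them higher and 512 lower in compost, where chance gives 1421. The other 2 pairings of the arrays had more, 1298 and 1784, and the pairing of both replicates 1 against both replicates 2 called 1 probe. A variance trend with robust estimation also gave 0 calls. In 80 probes both compost arrays lay at least 1 log2 unit above both control arrays, and in 44 both lay as far below. These pairings separated 107 and 135 probes in both directions together, against 124 for the real one. Without 1 array these counts were larger, since 3 arrays separate more readily: 175 to 359 upward and 158 to 338 downward, and without control replicate 2, 2 probes were called higher. With normexp background correction the counts were 21 and 7, without a filter on dim probes they were 114 and 122, and with all 4 arrays well above background they were 38 and 11.

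All 12 measured genes of the B and plasma cell list were higher in compost (camera adjusted p = 4.0e-13, and adjusted p = 0.386 with an estimated correlation). In 11 of them both compost rats lay above both control rats. Chance gives 16.7% for a single gene, but marker genes of a cell type can rise and fall together, so the 11 are not independent. None of the 12 passed on its own, over all genes or adjusted over the list alone. Its leading members were Cd22 (log2 difference 1.37 ± 0.30 SE, well above background in 1 of the 2 control rats), Cd79b (2.43 ± 0.64) and Cd72 (1.45 ± 0.42), which sit at the B cell surface, and Mzb1 (1.69 ± 0.49), a chaperone of antibody assembly. Cd79b lay at 1.55 without compost replicate 2 and Mzb1 at 1.09 without compost replicate 1. In the lymphoid follicle list 12 of 14 genes were higher, all 12 with both compost rats above both control rats, and the median was 1.04 (camera adjusted p = 5.9e-13; adjusted p = 0.386 with an estimated correlation). The estimated correlation between the follicle genes was 0.30, so the 12 cannot be counted as independent either. No member passed over all genes and 5 passed adjusted over the list alone. These were Cxcl13, the chemokine receptors Ccr6 (1.13 ± 0.19) and Ccr7, the lymphoid chemokine Ccl21 (0.80 ± 0.18) and Mfge8, with Mfge8 outside the rule for named genes and given after its value was seen (1.08). Ccr7 was not well above background in either control rat and was at least 1.84-fold higher in compost (1.25-fold with normexp). The 2 members that were lower were Gp2, a marker of the M cells over follicles (-1.12), and Bcl6 (-0.07), both also given after their values were seen.

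**Figure D3:**
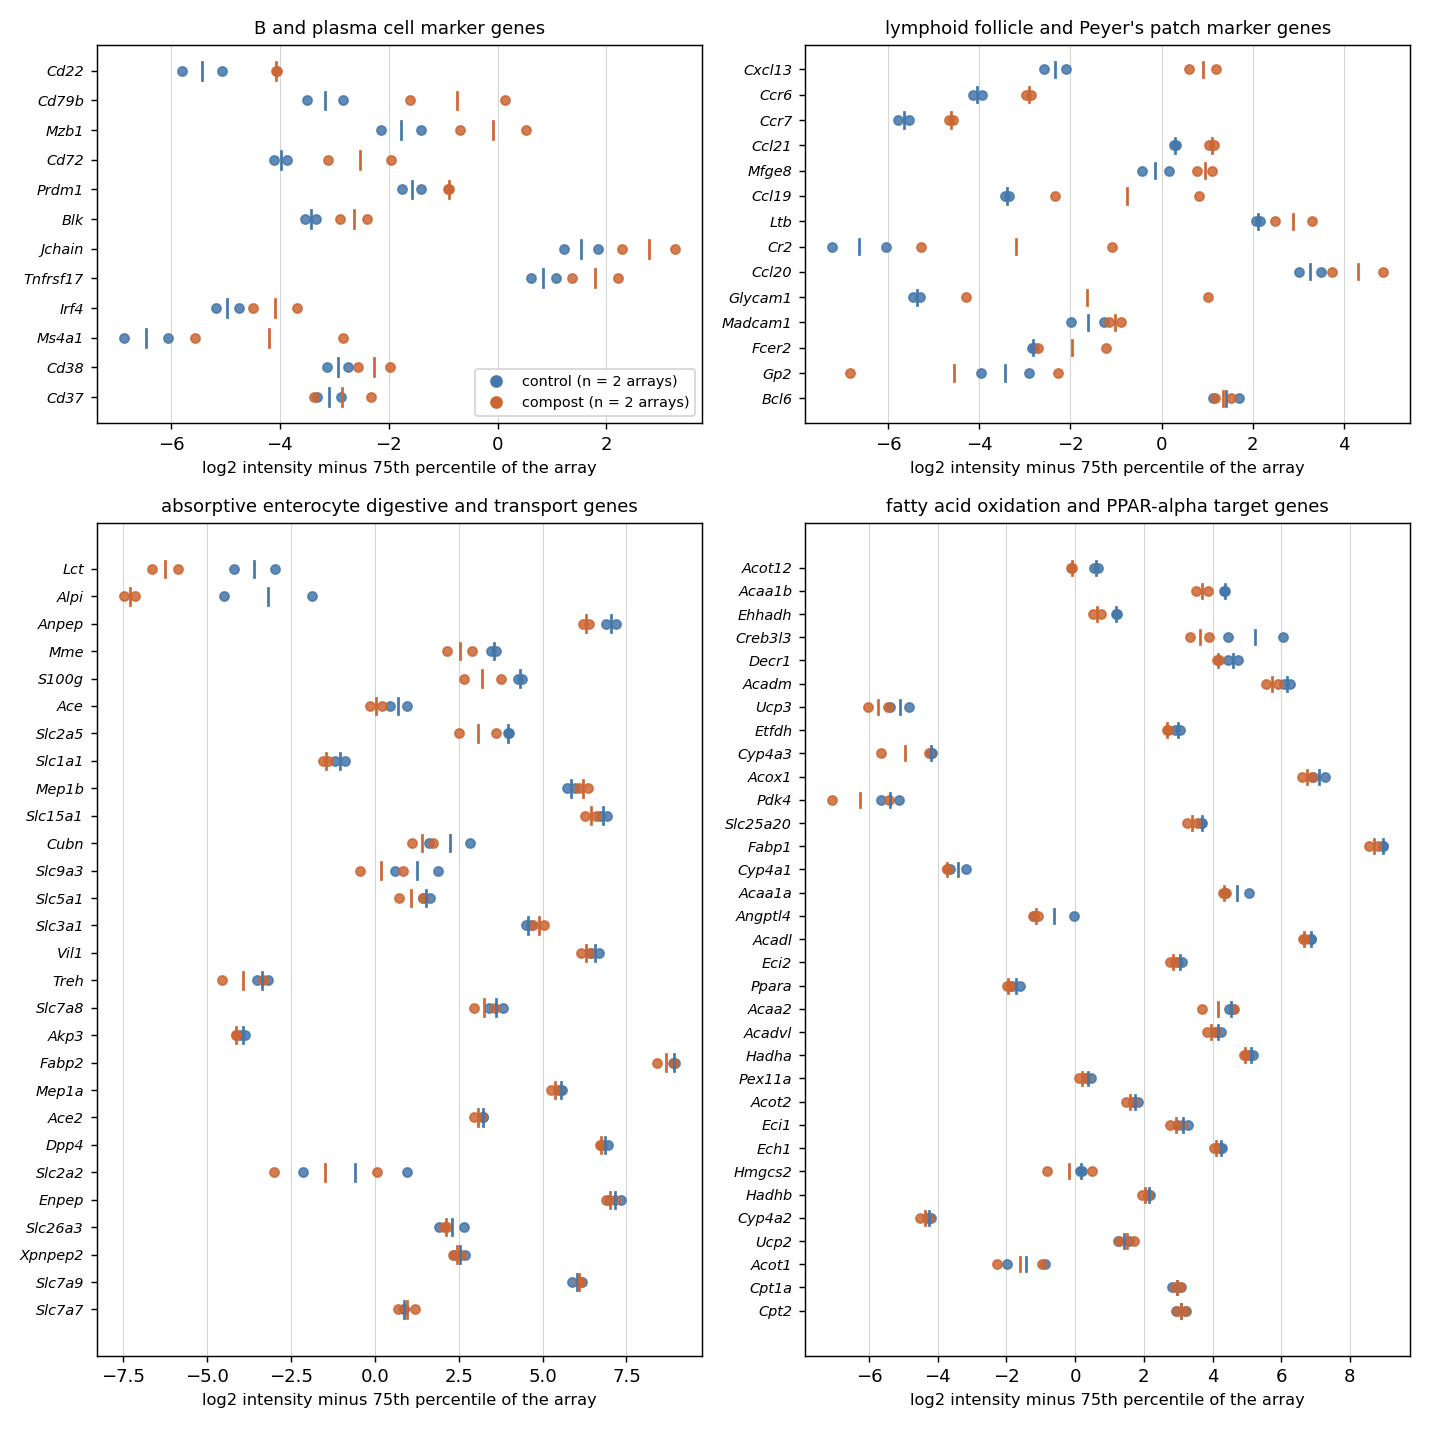
Log2 intensity minus the 75th percentile of the array (x axis) for the measured genes (y axis, by unadjusted p) of the B and plasma cell, lymphoid follicle, absorptive enterocyte and fatty acid oxidation lists; each point is 1 rat and a vertical line marks the mean of a group of 2 rats. In 11 of 12 B and plasma cell genes both compost rats lie above both control rats, and in 14 of 28 enterocyte genes both lie below.

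Other immune lists moved less. In the microbial sensing and inflammatory mediator list 26 of 36 genes were higher, with a median of 0.28 (camera adjusted p = 5.8e-07; adjusted p = 0.386 with an estimated correlation). It was led by the anti-inflammatory cytokine Il10 (1.44 ± 0.24 SE), the bacterial lipoprotein receptor Tlr2 (1.13 ± 0.27), interferon gamma, Ifng (0.92 ± 0.24), and the mucosal chemokine Ccl28 (0.96 ± 0.26). The MHC class II list, which serves antigen presentation to helper T cells, had 12 of 13 genes higher and a median of 0.18 (camera adjusted p = 4.6e-04; adjusted p = 0.517 with an estimated correlation). Its leading members were Cd40 (0.87 ± 0.18) and RT1-DOa (0.61 ± 0.20), and the call was lost without control replicate 2 (adjusted p = 0.104). Macrophage and dendritic cell markers were higher in 19 of 21 genes with a median of 0.55 (camera adjusted p = 1.8e-06; adjusted p = 0.611 with an estimated correlation). Among them were the Fc receptors Fcgr2b (1.17 ± 0.25) and Fcgr3a (1.90 ± 0.59, and 1.20 without compost replicate 1). Without compost replicate 1 their median was 0.06 and the call was lost (adjusted p = 0.669). The pairing of both replicates 1 against both replicates 2 gave a larger median in size, -0.62, and called the list (adjusted p = 7.2e-08). T cell markers were higher in 14 of 21 genes with a median of 0.08 and were not called (adjusted p = 0.111). Cd2 alone passed adjusted over that list alone. The T cell median was 0.53 without control replicate 1, -0.45 without control replicate 2, 0.20 without compost replicate 1 and -0.09 without compost replicate 2. Its direction thus depended on which rat was left out. Cytotoxic and natural killer cell markers were higher in 11 of 18 genes with a median of 0.09 (adjusted p = 0.50). This median also turned, at 0.49 without control replicate 1 and -0.37 without control replicate 2. Interferon response genes were split at 22 higher and 21 lower (median 0.01, adjusted p = 0.431). They had a median of 0.20 without control replicate 1 (adjusted p = 1.4e-04), -0.15 without control replicate 2 (adjusted p = 0.0410) and 0.09 without compost replicate 2 (adjusted p = 0.0243). Genes of type 2 immunity had a median of -0.18 (adjusted p = 0.671).

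Lower in compost were genes of nutrient uptake and lipid handling. In the absorptive enterocyte list 24 of 28 genes were lower, with a median of -0.36 (camera adjusted p = 1.8e-06; adjusted p = 0.386 with an estimated correlation). The median was -0.20 without compost replicate 1 and -0.52 without control replicate 2. The lactase gene Lct and the intestinal alkaline phosphatase gene Alpi were not well above background in either compost rat and were at least 4.01-fold and 5.34-fold lower. Without control replicate 1 these bounds were 2.63-fold and 2.14-fold, and with normexp background correction the measured folds were 1.60 and 2.35. The brush border peptidase genes Anpep and Mme differed by -0.75 ± 0.21 SE and -1.02 ± 0.31. Fatty acid oxidation genes and targets of the lipid sensor PPAR-alpha were lower in 30 of 33 cases with a median of -0.28 (camera adjusted p = 1.9e-07; adjusted p = 0.386 with an estimated correlation). The acetyl-CoA thioesterase gene Acot12 (-0.71 ± 0.18), the peroxisomal thiolase gene Acaa1b (-0.66 ± 0.21), the peroxisomal enzyme gene Ehhadh (-0.56 ± 0.19) and the transcription factor gene Creb3l3 (-1.61 ± 0.58, and -0.81 without control replicate 1) led that list. Lipid absorption and lipoprotein genes were lower in 23 of 27 cases with a median of -0.43 (camera adjusted p = 5.3e-05; adjusted p = 0.611 with an estimated correlation). They were led by the chylomicron apolipoprotein genes Apoa4 (-1.60 ± 0.39) and Apoc2 (-0.64 ± 0.22). That call was lost without control replicate 1 (median -0.20, adjusted p = 0.341), and both other pairings of the arrays also called this list, with medians of -0.12 (adjusted p = 0.0279) and -0.44 (adjusted p = 3.8e-03). Xenobiotic metabolism genes were lower in 34 of 45 cases with a median of -0.24 (camera adjusted p = 2.9e-03; adjusted p = 0.611 with an estimated correlation). Cyp4f1 differed by -0.77 ± 0.21, and Cyp2d3, not well above background in either compost rat, was at least 1.90-fold lower (1.18-fold with normexp), while the quinone reductase gene Nqo1 differed by 1.00 ± 0.32 upward. The call was lost without control replicate 1 (median -0.10, adjusted p = 0.341) and without compost replicate 1 (adjusted p = 0.0594). No member of these 4 lists passed over all genes or adjusted over the list alone. Beside them, epithelial junction genes had a median of -0.06 (9 higher and 17 lower, adjusted p = 0.788), and the markers of B cells and macrophages lay at 1.10 and 0.55. Proximal small intestine markers were split at 6 higher and 7 lower (median -0.03, camera adjusted p = 0.294). Their mean was -0.53 and their lower quartile -1.60. In 4 of them both compost rats lay below both control rats, and in 1 both lay above. Their median was -0.32 without control replicate 2 and 0.19 without control replicate 1. Distal markers were 9 higher and 7 lower (median 0.06, adjusted p = 0.931), with a mean of the opposite sign, -0.14.

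Sterol biosynthesis genes were higher in 22 of 25 cases, with a median of 0.28 (camera adjusted p = 2.8e-08, and adjusted p = 0.592 with an estimated correlation). In 16 of them both compost rats lay above both control rats, against a chance share of 16.7% for a single gene. The estimated correlation between these genes was 0.42, so the 16 are not independent. Fdft1 and Sqle, which make and oxidise squalene, differed by 0.64 ± 0.18 SE and 0.71 ± 0.27, and Fdps, which makes farnesyl diphosphate, by 0.61 ± 0.20. The median was 0.17 to 0.45 without 1 array, and the pairing of both replicates 1 against both replicates 2 also called this list, with a median of 0.24 (adjusted p = 0.0279). Unfolded protein response and endoplasmic reticulum chaperone genes were higher in 19 of 23 cases with a median of 0.20 (camera adjusted p = 2.2e-03; adjusted p = 0.386 with an estimated correlation). Among them were Hyou1 (0.44 ± 0.17) and Creld2 (0.49 ± 0.24). Cell cycle and DNA replication genes were higher in 33 of 37 cases with a median of 0.17 (camera adjusted p = 3.8e-05; adjusted p = 0.667 with an estimated correlation). Tyms differed by 0.54 ± 0.23 and Cenpf by -0.49 ± 0.21. That call was lost without control replicate 1 (median 0.05, adjusted p = 0.170) and without compost replicate 1 (adjusted p = 0.0891), and 1 other pairing of the arrays also called the list, with a median of 0.19 (adjusted p = 3.8e-03). Intestinal stem cell and Wnt genes were not called (median 0.04, adjusted p = 0.724). No member of these 4 lists passed over all genes or adjusted over the list alone.

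Secretory lineages were called with less support. Goblet cell and mucus genes were higher in 14 of 16 cases with a median of 0.20 (camera adjusted p = 2.6e-03; adjusted p = 0.386 with an estimated correlation). They were led by the mucin glycosyltransferase gene Gcnt3 (0.78 ± 0.25 SE), and the call was lost without compost replicate 1 (adjusted p = 0.193). Paneth cell and secreted antimicrobial genes were higher in 10 of 14 cases with a median of 0.48 (camera adjusted p = 9.4e-03; adjusted p = 0.808 with an estimated correlation). Nos2, the inducible nitric oxide synthase, was not well above background in either control rat and was at least 3.27-fold higher (1.64-fold with normexp). Without control replicate 1 the Paneth cell median was -0.09 (adjusted p = 0.557), and the call was also lost without compost replicate 1 (adjusted p = 0.205) and without compost replicate 2 (adjusted p = 0.0773). Another pairing of the arrays also called the list, with a median of 0.35 (adjusted p = 7.3e-03). Enteroendocrine hormone genes were higher in 15 of 21 cases with a median of 0.20 (camera adjusted p = 0.0376; adjusted p = 0.517 with an estimated correlation). Among them were the serotonin synthesis gene Tph1 (0.41 ± 0.18) and the secretin gene Sct (0.50 ± 0.23). That call was lost without control replicate 2 (adjusted p = 0.325) and without compost replicate 1 (adjusted p = 0.400), and also with quantile (adjusted p = 0.0512) and cyclic loess scaling (adjusted p = 0.0634). No member of these 3 lists passed over all genes or adjusted over the list alone.

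Markers of other cells in the wall were measured beside these groups. Neutrophil markers were higher in 6 of 7 genes with a median of 0.93 (camera adjusted p = 0.0308; adjusted p = 0.592 with an estimated correlation). Without control replicate 1 the median was -0.03 (adjusted p = 0.268), and the call was also lost without compost replicate 1 (adjusted p = 0.205) and without compost replicate 2 (adjusted p = 0.365). It was lost as well without a filter on dim probes (median 0.0093, adjusted p = 0.989) and with all 4 arrays well above background (adjusted p = 0.0978). Mast cell markers were higher in 13 of 18 genes with a median of 0.43 (camera adjusted p = 0.0274; adjusted p = 0.808 with an estimated correlation). Fibroblast and matrix markers were higher in 21 of 24 genes with a median of 0.22 (camera adjusted p = 0.0457; adjusted p = 0.926 with an estimated correlation). Without compost replicate 1 both turned downward, to -0.03 (adjusted p = 0.228) and -0.35 (adjusted p = 2.5e-04), and without control replicate 2 both calls were lost (adjusted p = 0.695 and 0.451). The mast cell call was lost with cyclic loess scaling (adjusted p = 0.0634), and the fibroblast call with quantile scaling, cyclic loess scaling and normexp background correction (adjusted p = 0.125, 0.171 and 0.0942). Both were also called, with larger medians in size, in the pairing of both replicates 1 against both replicates 2, at -0.97 (adjusted p = 1.1e-08) and -0.66 (adjusted p = 1.4e-12), and the fibroblast list in the crossed pairing too (median 0.44, adjusted p = 1.5e-04). Not called were smooth muscle markers (14 higher and 7 lower, median 0.16, adjusted p = 0.111), endothelial markers (11 higher and 4 lower, median 0.11, adjusted p = 0.355), and erythroid markers of blood (3 higher and 2 lower, median 0.38, adjusted p = 0.334). The same held for enteric neuron and glia markers (9 higher and 14 lower, median -0.08, adjusted p = 0.593), adipose markers (6 higher and 6 lower, median -0.02, adjusted p = 0.788) and pancreas acinar markers (7 higher and 9 lower, median -0.14, adjusted p = 0.932). Of these, the endothelial list was called higher without compost replicate 2 (median 0.53, adjusted p = 4.9e-05) and without control replicate 1 (median 0.30, adjusted p = 0.0157), and lower without compost replicate 1 (median -0.31, adjusted p = 9.8e-03). The neuron and glia list was called higher without compost replicate 2 (median 0.29, adjusted p = 0.0117), and lower without compost replicate 1 (median -0.42, adjusted p = 8.1e-05) and without control replicate 1 (median -0.28, adjusted p = 0.0297). The smooth muscle list was called higher without control replicate 2 (adjusted p = 3.1e-03) and without compost replicate 2 (adjusted p = 2.6e-03), and the erythroid list without control replicate 1 (adjusted p = 1.5e-05) and without a filter on dim probes (adjusted p = 0.0106).

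Lists of handling, of stress and of the circadian clock did not pass in the setting used throughout. The medians were 0.04 for hypoxia and glycolysis genes (adjusted p = 0.0777), 0.07 for antioxidant and NRF2 target genes (adjusted p = 0.0777), 0.06 for heat shock chaperone genes (adjusted p = 0.355), 0.02 for immediate-early genes (adjusted p = 0.577), -0.03 for mitochondrial oxidative phosphorylation genes (adjusted p = 0.817) and -0.12 for circadian clock genes (adjusted p = 0.554). Hypoxia and glycolysis genes and antioxidant and NRF2 target genes were called higher with normexp background correction (adjusted p = 0.0436 for both). The hypoxia and glycolysis genes were also called higher with a variance trend and robust estimation (adjusted p = 0.0396) and without control replicate 1 (adjusted p = 0.0484), and oxidative phosphorylation genes lower without compost replicate 2 (adjusted p = 0.0478). Genes that transport and sense short-chain fatty acids and lactate had a median of 0.05 and a mean of -0.02 (adjusted p = 0.932). Of the 39 lists, 37 had no member that passed adjusted over the list alone, and the follicle and T cell lists had 5 and 1.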

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

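The 18 alternatives were planned before the data were examined. The replicate number as a block left 0 probes called in either direction and 14 and 4 lists called higher and lower. Over all probes kept, same-numbered arrays of the 2 groups did not deviate together (correlation of their deviations -0.04), and the labels treat them as different rats. Single lists could differ from this: the pairing of both replicates 1 against both replicates 2 called 14 lists, and the crossed pairing called 9. Mast cell medians, relative to the mean of the 4 arrays, were -0.02 (control) and 0.85 (compost) in replicates 1. In replicates 2 they were -0.65 and -0.39. With each array left out in turn, the lone array of a group being assumed to vary like the pair of the other, the called probes ranged from 0 to 2 higher and stayed at 0 lower. The 2 probes, both without control replicate 2, were Gzmb, named after its value was seen, and an unnamed transcript. Gzmb lay at -3.84 in control replicate 1 and between 3.47 and 4.98 in the other rats. The separated probes ranged from 175 to 359 upward and from 158 to 338 downward, since 3 arrays separate more readily, and the lists called from 6 to 17 higher and from 3 to 8 lower. Mast cell and fibroblast markers turned downward without compost replicate 1, to medians of -0.030 and -0.35, and lay at 1.02 and 0.80 without compost replicate 2.

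Normexp background correction gave 21 probes separated upward and 7 downward, 75% of them upward against 64.5%. With no filter on dim probes the counts were 114 upward and 122 downward, or 48.3% upward. Where all 4 arrays had to be well above background they were 38 and 11, or 77.6% upward, so that dim signal limits these counts. With 1 array left out the upward share was 45.9% to 58.2%, so the excess upward was not stable. The estimated correlation and fry each called 0 lists higher and 0 lower. For the estimated correlation the simulated data gave 0 calls for a shift of 1 log2 unit too; for fry the cause was not tested. Under the other scalings and filters 11 to 15 lists were higher and 4 lower. Of the 18 calls, 15 were made under all 5 scalings and 17 under all 3 filters. No scaling moved the median of all probes by over 0.1 log2, but each scaling first aligns the arrays, so this is not a test of the scaling. All 346 values of the 24 named genes under alternatives kept their direction and none passed, but all 24 were smaller with normexp. Of 21 lists not called, 17 changed direction under at least 1 alternative.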

Other observations

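The tests and added gene sets of this part were chosen after the results were seen. The fixed lists and the scaling and background alternatives that they draw on were planned. Immunoglobulin transcripts, which the fixed lists did not hold, were higher in compost. Of 55 probes described on the array as an immunoglobulin chain, 49 were higher and 6 lower, with a median log2 difference of 1.44. It was 1.34 with bounds for the 5 probes not well above background in 1 group. In 29 probes both compost rats lay above both control rats, and in 2 both lay below. Chance gives 16.7% in each direction for a single probe, but these probes were chosen for their values and can vary together, so the count is not a test. None passed limma's test adjusted over all probes, and 23 had an unadjusted p under 0.05 and were higher. No p is given for the set, since it was chosen for its values. With normexp background correction its median was 0.94. The other 2 pairings of the arrays gave medians of 0.04 and 0.88 in size. Of 6 probes for gamma heavy chains, the chains of IgG, 5 had both compost rats above both control rats and 1 differed by 0.06. Of these, the gamma-2a constant region probe was not well above background in either control rat and was at least 8.54-fold higher (2.60-fold with normexp). With that bound the median log2 difference of the 6 was 2.59, and it was 1.33 with normexp background correction. The probe for the delta chain of IgD, found on naive B cells, was also not well above background in either control rat and was at least 5.45-fold higher, or 3.00-fold without compost replicate 1 (2.35-fold with normexp). The 24 light chain probes had a median log2 difference of 1.17, with 22 of them higher.

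The higher level of B cell and follicle genes was weighed against 3 explanations. The scalings and background corrections tried did not remove it. The median of these genes was 1.04 in the setting used throughout. At the lowest over 5 other scalings and background corrections it was 0.72, above the bound of 0.5. They cannot separate an effect of array position, since position and group coincide. More organised follicle tissue in the compost pieces may account for it: the median of 10 genes of mature B cells exceeded that of 6 plasma cell genes by 0.33, but the 95% bootstrap interval over genes ran from -0.40 to 1.34, so that follicle and plasma cell contributions cannot be told apart. The labels exclude Peyer's patches without saying how fully they were removed, and patch tissue left in the compost pieces, or small isolated follicles, could give the same difference. Of the 3 pairings of the arrays, 1 gave a median as large, the real one, with 0.34 as the highest of the others. These 3 pairings are too few for a share under 0.05. The treatment remains an untested explanation beside differences between individual rats and array position, which cannot be told apart from group.

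The lower level of enterocyte genes was weighed in the same way. A smaller share of epithelium in the compost pieces would lower all epithelial genes. However, 17 genes shared by epithelial cells, such as Epcam, Cdh1 and Krt8, had a median of -0.015 against -0.36 for the enterocyte list. The 95% bootstrap interval over these genes was -0.052 to 0.094. It holds the spread between genes and not that between rats. A more distal piece of intestine could lower Lct and Apoa4. Distal markers exceeded proximal markers by 0.095 in the median, with an interval of -0.31 to 1.71 that decides nothing. Lct belongs to both the proximal and the enterocyte list, so the proximal list is not independent of the pattern. Of the 3 pairings, 1 gave a median as large in size, the real one, with 0.12 as the highest of the others, again too few pairings for a share under 0.05. An effect of the treatment on mature enterocytes stays open and untested, beside differences between individual rats and in array position.

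Probes well above background in both rats of 1 group and neither rat of the other, and at least 3 log2 units apart, included those of Doc2b, Nova1 and Muc19. There were 27 of them, 19 higher and 8 lower in compost, and the highest count in the other pairings was also 27. Of the 3 pairings, 2 gave a count as large, and 3 are too few for a share under 0.05. Sequence differences between outbred rats under a probe were not tested.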
